A study of Sparus aurata with 34 samples.

How the data were processed

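Total RNA of heart, white muscle and red muscle was amplified from 100 ng per sample, labelled with Cy3 together with a spike-in kit and hybridised to 1-colour Agilent arrays, per the labels' protocols. The labels speak of individual samples; nothing used here says which tissues came from the same fish, so p-values measure the spread between these samples. The deposited scanner files hold intensity values per spot, which the authors extracted with Agilent Feature Extraction 10.7.3.1 per the file headers, while the submitters' processing notes name version 10.4.0.0. The processed signal in them is background-corrected and not yet scaled between arrays. The authors' deposited series table holds log2 values. Set against the scanner values, it matched a 75th percentile shift with each probe centred on its median over the arrays (slopes 0.963 to 1.00, correlations 0.980 to 1.0), and its column medians ran from -0.28 to 0.51. Its log base, scale and direction were found from this comparison, as no source used here states them.

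The array has 45220 spots, of which 43803 are not controls and stand for 28793 probes of 15156 contig or clone identifiers. None of these identifiers matched the 32006 genes of the reference gene table (0 matched), so no gene name is used, and the gene lists and gene set tests fixed before the data were examined were not run. Spots marked as outliers were left out and spots of a probe averaged. The log2 of the processed signal minus the 75th percentile of each array was tested. Probes had to be well above background on at least 4 arrays, which kept 22036 probes of 11964 identifiers; 8375 were well above background on every array.

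All 34 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) with 6 tissue-by-ration means and 28 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Contrasts were the ration effect in each tissue, its differences between tissues, and the tissue differences at full ration. The rule for named genes took the largest rises and falls among passing probes that were well above background on every array of the higher group, with 1 probe per identifier, its brightest. As the identifiers have no names, the text prints at most 2 that rose and 2 that fell per comparison. The files were read with Python 3.11.15 and figures drawn with matplotlib 3.10.9.

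The fit was tested on simulated data with 200 changed probes among 22036. Every array had the means of full-ration hearts and the real spread of each probe, as independent normal noise. The data held no scan day, slide or pairing effect and no signal floor, so the shares recovered describe the fit alone. Of 2-unit log2 changes it recovered 87.5% in heart, 90.5% in white muscle and 90.5% in red muscle, and of 1-unit changes 42.0%, 36.0% and 52.5%. The direction of the set test was tested in the same way.

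Whether the replicate numbers pair the arrays was checked by the correlation of deviations from the group means. For red and white muscle at full ration all 5 same-numbered pairs were over 0.1 (0.20 to 0.37), which was taken as pairing from the data. Some differently numbered pairs of these groups were over 0.1 too. White muscle 6 and 8 each gave 0.20 with red muscle 3, all of scan day 5, which the check did not remove. No source used here says that a number marks a fish, and the reported fit did not use the pairs. In every other pair of groups a same-numbered pair was at 0.1 or below, or fewer than 3 pairs were at hand. Pairing was not taken there and stays open.

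Scan day and slide, taken from the file headers, were tested as batches. Slides holding both rations of a tissue have 1 array of one of them, too few for a test within a slide; values from the slide of heart arrays that holds both rations rest on 1 maintenance array. Alternatives covered background correction, scaling, the filter, the test, array weights, blocks, the authors' values and leaving out each array. The files hold no mean signal column, so normexp (offset 50) was run on the median signal and median background. Alternatives on scan day, the spike-in, a random slide block, single-array scan days and arrays with a larger spread after normexp were chosen after seeing the data.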

Results

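Gene expression was measured in 3 tissues of gilthead sea bream, a farmed marine fish, after 11 weeks on a full ration or on a maintenance ration of 30% of satiation. The tissues were heart and red skeletal muscle, which work aerobically, and white skeletal muscle, which works largely anaerobically. The 34 arrays comprised 4 hearts at maintenance and 7 at full ration, 5 white muscles at each ration, and 5 red muscles at maintenance and 8 at full ration. The comparisons ask how each tissue responded to the smaller ration, whether the responses differed between tissues, and how the tissues differed at full ration. The files do not pair the array's contig and clone identifiers with gene names, so results are given for probes and identifiers. The number of arrays limits the precision of every value.

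Signal over background differed between groups. On average 56.8% of probes (SD 9.73, n = 4) were well above background in maintenance hearts and 70.4% (SD 4.995, n = 7) in full-ration hearts. The shares were 46.5% (SD 4.90, n = 5) and 46.97% (SD 2.98, n = 5) in white muscle, and 53.1% (SD 4.26, n = 5) and 61.7% (SD 6.57, n = 8) in red muscle. Arrays were scanned on 5 days, and ration and scan day were unevenly combined. Heart had 3 maintenance and 7 full-ration arrays on scan day 1 and 1 maintenance array on scan day 3. White muscle had 3 arrays of each ration on scan day 5, with 2 full-ration arrays on day 1 and 2 maintenance arrays on day 2. In red muscle all 5 maintenance arrays were scanned on day 5 with 1 full-ration array, and the other full-ration arrays on days 2 and 4.

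**Figure D1:**
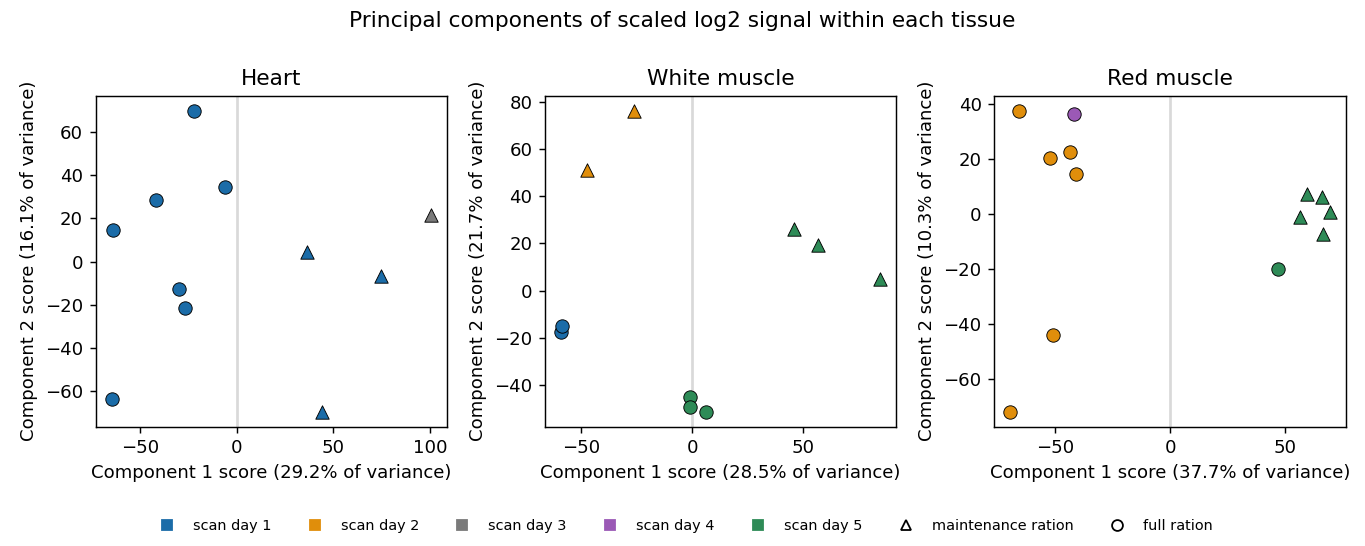
Scores of each array on principal components 1 and 2 of the scaled log2 signal, computed within each tissue; each point is 1 array, its colour the scan day and its shape the ration. In red muscle the full-ration array of scan day 5 scored 46.7 on component 1, on the side of the maintenance arrays (56.5 to 69.4).

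In the heart, the maintenance ration changed 5286 of 22036 probes, 2468 upward and 2818 downward (limma, adjusted p under 0.05). The changed probes belonged to 3357 of 11964 identifiers. The balance of directions depended on the scaling: within scan day 1, 49.5% of 3365 called probes were higher, against 0.43% of 11997 when each array was scaled to its spike-in, RNA of known dose added to each sample. Of the changed probes, 1107 rose and 1009 fell at least 2-fold. Clone cDN06P0005L18.F.ab1 rose by 4.36 on the log2 scale (SE 0.87, adjusted p = 0.000701, limma). Its scaled log2 signal was 1.10 ± 0.73 (SD, n = 4) at maintenance and -3.26 ± 2.11 (SD, n = 7) at full ration, where it was well above background on 5 of 7 arrays, and all 3 of its probes passed. Contig1322 rose by 3.80 (SE 0.61, adjusted p = 0.000107, limma) and was well above background on 1 of 7 full-ration arrays. Contig532 fell by 5.01 (SE 1.44, adjusted p = 0.0118, limma), with values at full ration spread over -0.25 ± 3.47 (SD, n = 7) that overlapped those at maintenance. Contig1645 fell by 4.39 (SE 1.03, adjusted p = 0.00295, limma), and all 3 of its probes passed. Both falling identifiers were well above background on 1 of 4 maintenance arrays.

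With scan day as a block the heart comparison called 4398 probes. With slide as a block it called 213, and none of the 4 identifiers above passed. There the called fold changes kept a median 0.75 of their size, while the median SE rose from 0.28 to 0.44. That contrast rests on 1 maintenance array. Without maintenance replicate 7, the only array of its scan day, 3188 were called, and 1320 after normexp background correction. The normexp count rose above the reported one without the 3 arrays whose spread normexp enlarged.

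In white muscle, the maintenance ration changed 2693 of 22036 probes, 1475 upward and 1218 downward (limma, adjusted p under 0.05), from 1721 identifiers. Of these probes 616 rose and 446 fell at least 2-fold. Clone cDN10P0005I23.F.ab1 rose by 3.99 on the log2 scale (SE 0.84, adjusted p = 0.00192, limma). In red muscle its change was 2.498 (SE 0.76, adjusted p = 0.0183, limma), and 1.17 within scan day 5. It was well above background on 3 of 5 full-ration white muscle arrays, and CUST_6707_PI419285025 on 4 of 5. Probe CUST_6707_PI419285025 rose by 3.77 (SE 0.79, adjusted p = 0.00177, limma), from -0.40 ± 1.58 (SD, n = 5) at full ration to 3.37 ± 0.71 (SD, n = 5) at maintenance. Probe CUST_7161_PI419285597 fell by 3.70 (SE 0.61, adjusted p = 0.000126, limma), and clone cDN09P0001L11.F.ab1 fell by 3.69 (SE 0.65, adjusted p = 3e-04, limma). Each of these falling identifiers was well above background on 1 of 5 maintenance arrays. The arrays of the rations overlapped for cDN09P0001L11.F.ab1, in which maintenance replicate 8 stood at -0.35.

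Within scan day 5, with 3 arrays of each ration, 424 probes were called, and 398 of them had the same direction in the 4 arrays of the other days (93.9%, against 60.4% of all tested probes), where ration and day coincide. Of these 424 probes 46.2% were higher, against 11.3% of 328 when each array was scaled to its spike-in. The count was 2529 with scan day as a block and 897 with slide as a block. It was 908 when only white muscle entered the fit and 179 after normexp background correction. Splitting the white muscle arrays by scan day, with the rations balanced on both sides, called 2173 probes. The normexp count rose without the 3 arrays whose spread normexp enlarged, but stayed below the reported one.

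In red muscle, the maintenance arrays differed from the full-ration arrays in 4999 of 22036 probes, 2853 higher and 2146 lower (limma, adjusted p under 0.05). After median centring 46.3% of the called probes were higher, against 57.1% as reported. With scan day as a block the count was 145, and within scan day 5, with 5 maintenance arrays and 1 full-ration array, it was 12, of which 4 were higher, against 2 of 13 scaled to the spike-in. Clone cDN04P0004I22.F.ab1 was higher by 4.91 on the log2 scale (SE 1.04, adjusted p = 0.00141, limma), and clone cDN03P0005F15.F.ab1 by 4.58 (SE 0.73, adjusted p = 0.000151, limma). Within scan day 5 these values were -0.72 and -0.55, so their direction turned, and neither passed. Both were well above background on 2 of 8 full-ration arrays. Clone cDN11P0005D24.F.ab1 fell by 3.36 (SE 0.46, adjusted p = 1.78e-05, limma), and clone cDN11P0006J21.F.ab1 fell by 3.52 (SE 0.58, adjusted p = 0.000222, limma). Both still passed with scan day as a block, at -3.73 (SE 0.65, adjusted p = 0.0104, limma) and -4.43 (SE 0.83, adjusted p = 0.0116, limma). All 3 probes of each had passed without that block. The block assumes the same scan day effect in every tissue. Only scan day 5 held both rations of red muscle, with 1 full-ration array. Within it these clones differed by -3.37 and -2.94. They were well above background on 1 and 2 of 5 maintenance arrays. With slide as a block 11 probes were called in red muscle.

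**Figure D2:**
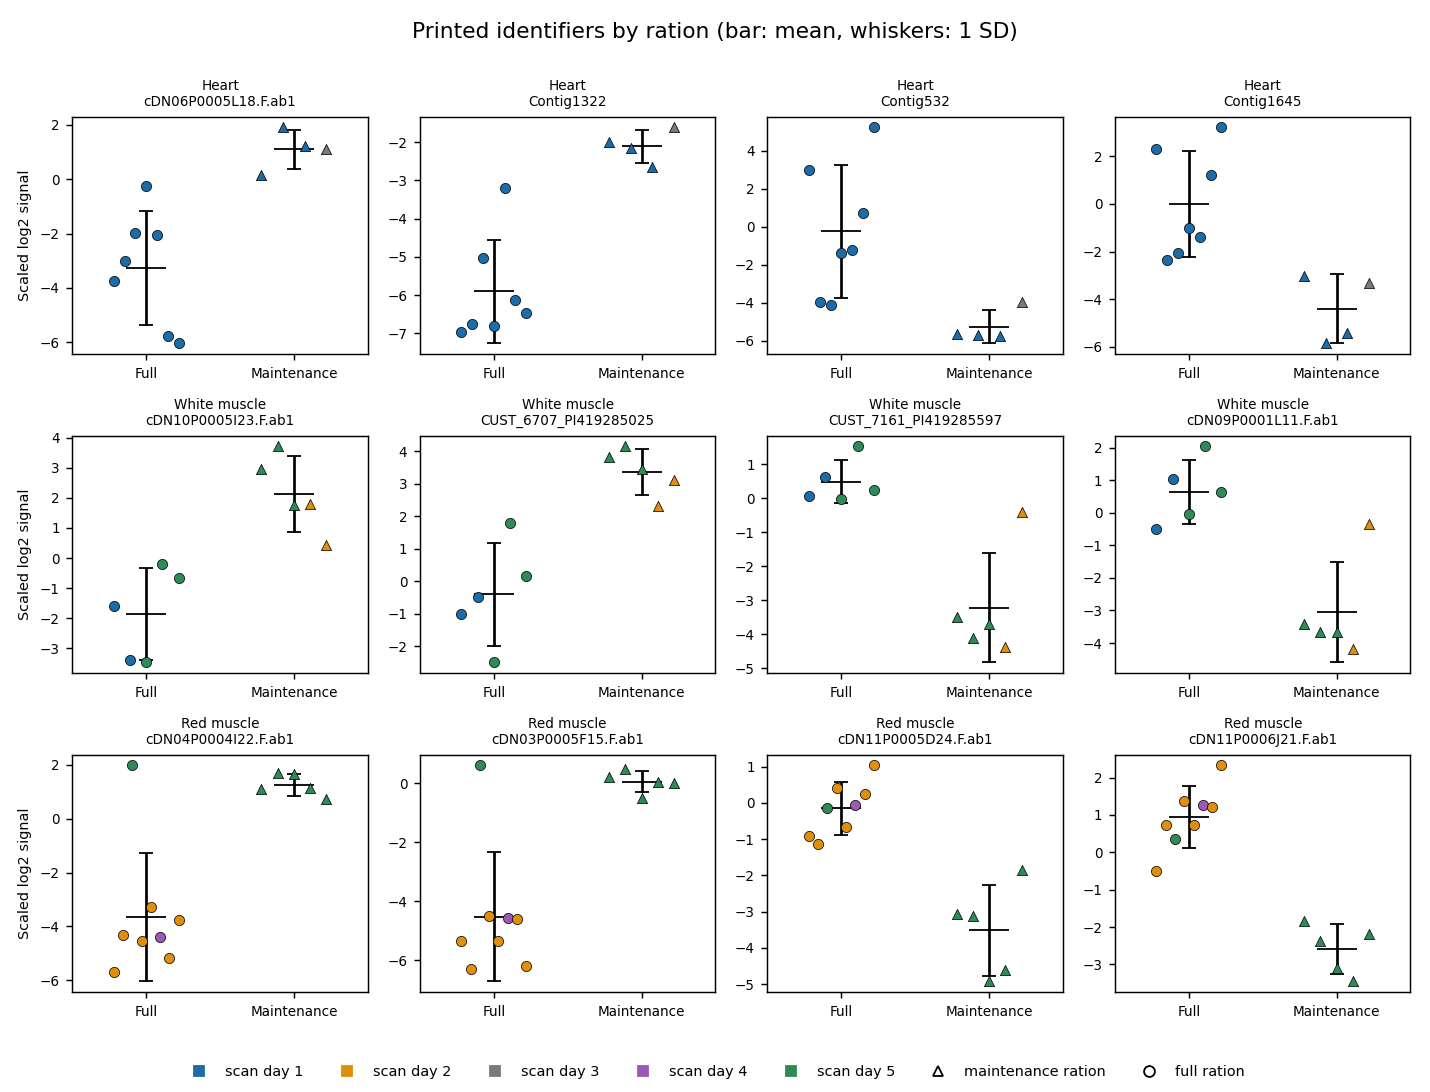
Scaled log2 signal of the printed identifiers in each array of the tissue in which they were chosen, by ration; points are arrays coloured by scan day, the bar is the group mean and the whiskers 1 SD. In red muscle, the full-ration array of scan day 5 lay at 1.97 for cDN04P0004I22.F.ab1, with the maintenance arrays, whose mean was 1.26.

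Differences between the rations overlapped between tissues, which share no array but have replicate numbers in common. In red muscle ration and scan day cannot be told apart for most called probes. Of the probes called in heart and white muscle, 461 were higher in both at maintenance, against 165.2 for independent lists, and 485 were lower in both, against 155.8; 86 went in opposite directions. Across all tested probes the fold changes correlated with r = 0.31, and with r = 0.35 when each tissue was taken within its main scan day. Probes are not independent replicates. From arrays with no replicate number in common within a ration r was 0.0954 for heart and white muscle, with 3 full-ration hearts and 2 maintenance white muscles. Of 350 choices of as many arrays, 35 gave a value as low. Within scan days r was 0.169, with 1 maintenance heart. With no number in common, arrays of heart and red muscle gave 0.418, which rests on 1 full-ration red muscle array. That was the only array of scan day 4. Within scan days heart and red muscle gave 0.0574. White and red muscle gave 0.342, and 0.221 within scan days. Heart and red muscle shared 832 higher probes, against 319.5 for independent lists, and 845 lower, against 274.4. White and red muscle shared 411 higher, against 191 for independent lists, and 453 lower, against 118.6. The correlation was 0.51 for heart and red muscle and 0.09 within scan days, and for white and red muscle 0.25 and 0.21. All values of red muscle within scan days rest on 1 full-ration red muscle array.

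The size of the response differed between tissues for some probes. Heart and white muscle differed in 1110 probes, heart and red muscle in 614, and red and white muscle in 1241 (limma interaction, adjusted p under 0.05). Contig1322 rose more in heart than its change in white muscle by 3.72 (adjusted p = 0.0115, limma) and in red muscle by 3.31 (adjusted p = 0.0243, limma). Contig1322 was well above background on no white muscle array and on 1 of 8 full-ration red muscle arrays. For identifiers that fell in white or red muscle a difference of response could hardly be measured, since they were dim in the other tissues already at full ration. CUST_7161_PI419285597 was well above background there on 2 of 7 hearts and 4 of 8 red muscles, and cDN11P0005D24.F.ab1 on 0 of 7 hearts and 0 of 5 white muscles. Among the 8375 probes well above background on every array, the responses differed in 891, 337 and 453. Within scan days, where red muscle has 1 full-ration array, the differences of Contig1322 were 3.27 (SE 0.95, from 0.86) and 4.71 (SE 1.15, from 0.82) and did not pass. With slide as a block neither passed, and that between heart and red muscle did not pass without heart maintenance replicate 7 or red muscle maintenance replicate 1. The 3 counts were 580, 60 and 36 within scan days, 410, 462 and 85 with scan day as a block and 30, 11 and 6 with slide as a block. After normexp background correction they were 20, 32 and 44, and without the 3 arrays whose spread was larger after it 1719, 443 and 7276. Leaving out 1 array gave 660 to 1235, 352 to 1000 and 697 to 1979, lowest without heart maintenance replicate 6 (660), heart maintenance replicate 7 (352) and white muscle maintenance replicate 7 (697). Without red muscle full-ration replicate 3 the last 2 counts were 1000 and 1979. For 35.1% and 51.5% of the called probes the log2 change at maintenance was higher in heart than in white and red muscle. After median centring these shares were 51.7% and 72.8%.

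The tissues differed far more than the rations. At full ration heart and white muscle differed in 14860 of 22036 probes, 7514 higher and 7346 lower in heart (limma, adjusted p under 0.05). Heart and red muscle differed in 11370 probes, 6036 higher and 5334 lower in heart. Red and white muscle differed in 12926, 6237 higher and 6689 lower in red muscle. No slide held full-ration arrays of more than 1 tissue, and full-ration hearts and red muscles shared no scan day. Tissue and batch therefore coincide for heart and red muscle. Values blocked by slide, and for that pair by scan day, rest on links through other groups. At a 2-fold minimum, 2275 probes were higher in heart than in both skeletal muscles, 1098 were higher in red muscle than in the other tissues and 3174 were higher in white muscle than in the others. Clone cDN02P0002F07.F.ab1 was not well above background on any full-ration heart array. On the scaled signal it was about 81570-fold higher in white muscle (adjusted p = 5.1e-23, limma). Clone cDN04P0003O02.F.ab1 was likewise not well above background in heart and was about 41930-fold higher in red muscle (adjusted p = 7.24e-19, limma). Clone cDN06P0001O20.F.ab1 was about 6990-fold higher in heart than in red muscle, where no array was well above background (adjusted p = 2.14e-28, limma). Each of these folds sets the brighter group's mean against a mean for the dimmer group. There each array gave the lowest signal among probes well above background or the probe's own signal, whichever was higher. For cDN02P0002F07.F.ab1 this equals the plain fold change. The folds are not lower bounds, since they depend on the scaling. The 75th percentile averaged 9.11 in full-ration hearts, 7.04 in full-ration white muscle and 8.78 in full-ration red muscle. Clone cDN13P0005K01.F.ab1 was higher in heart than in white muscle by 9.79 on the log2 scale (SE 0.47, adjusted p = 8.36e-18, limma) and was well above background on 2 of 5 white muscle arrays. Contig1974 was lower in red than in white muscle, with a log2 difference of -9.65 (SE 0.63, adjusted p = 1.39e-13, limma), and was well above background on 3 of 8 red muscle arrays. All these identifiers kept their direction and passed with scan day or slide as a block; the counts with slide as a block were 7085, 1791 and 7967.

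The signal of the tissue RNA relative to the spike-in was lower at maintenance in heart. Within scan day 1 the log2 ratio of the 75th percentile to the brightest spike-in was -1.42 ± 0.13 (SD, n = 3) at maintenance and -0.44 ± 0.36 (SD, n = 7) at full ration (2-sided exact permutation p = 0.00833, the smallest 120 splits can give, adjusted 0.025 over 3 tissues). In white muscle within scan day 5 it was -7.42 ± 0.16 (SD, n = 3) and -7.07 ± 0.37 (SD, n = 3) (2-sided exact permutation p = 0.2, adjusted 0.3). In red muscle within scan day 5 the difference was -0.41 against 1 full-ration array (2-sided exact permutation p = 0.333, adjusted 0.333), a design that cannot give a p under 0.167.

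**Figure D3:**
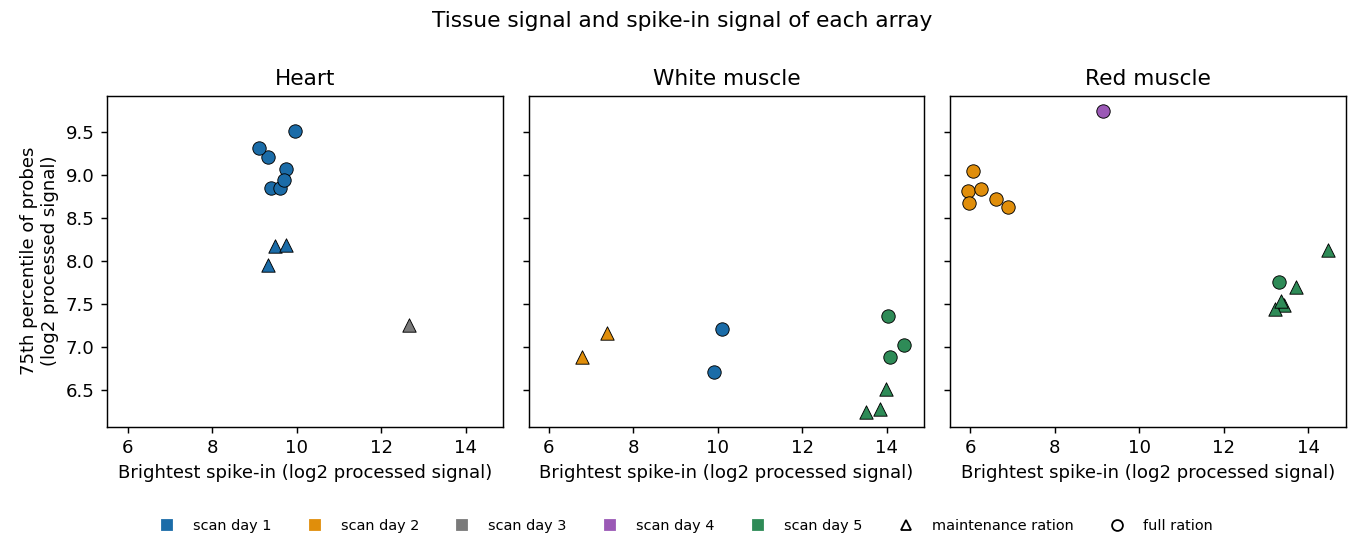
The 75th percentile of the log2 processed signal of each array against its brightest spike-in signal, by tissue; each point is 1 array, its colour the scan day and its shape the ration. Spike-in signal followed scan day, with means of 9.62 on day 1, 6.48 on day 2 and 13.8 on day 5.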

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

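The tests of scan day as the whole cause in red muscle, of dim arrays in heart and of scan day for the spike-in ratio were chosen after the result was seen.

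The red muscle response to ration coincided with scan day. Over the 4999 called probes, the red muscle difference without full-ration replicate 3 correlated with the difference between scan days 5 and 2 among white muscle arrays of 1 ration at r = 0.76, so scan day may account for much of it. The same probes correlated at r = 0.44 with the white muscle response within scan day 5, which a ration response could give. Both white muscle differences start from the same 3 maintenance arrays of scan day 5, so these correlations are not independent. The second could follow from the first and cannot tell ration from scan day. With scan day as a block, fold changes kept a median 0.42 of their size (quartiles 0.13 and 0.75), which lies between what the whole and none of the effect would leave, while the median SE rose from 0.25 to 0.34. Splitting the red muscle arrays by scan day called 5972 probes, more than the split by ration, so ration and scan day cannot be told apart for most of these probes.

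The heart response to ration was weighed against slide and brightness. With slide as a block the called fold changes kept a median 0.75 of their size (quartiles 0.51 and 1.00). Full-ration hearts lay on slides 3 and 4 only, and of these only slide 4 held a maintenance heart. The blocked value therefore rests on 1 maintenance array and cannot exclude slide as the whole cause. The count fell as the median SE rose from 0.28 to 0.44. On the slide with both rations, 84.7% of the 4328 probes called without it went the same way, against 67.8% of all tested probes. This rests on the same 1 maintenance array and leaves a slide effect open. Among probes well above background on every array 29.0% were called, against 23.99% of all tested probes. These probes lie above the signal floor by the way they were chosen. Their share cannot tell what the floor did to dimmer probes. Other effects of dimmer arrays were not tested. Ration and a slide effect may both contribute.

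The lower tissue signal over spike-in at maintenance in heart was not accounted for by scan day, since it held within scan day 1 (2-sided exact permutation p = 0.00833). On the slide with both rations the maintenance array minus the lowest full-ration array was -0.57, which rests on 1 array, so a slide effect may remain. As every sample was amplified from 100 ng of total RNA, the total RNA content of the tissue does not enter this ratio. A smaller yield of amplified RNA and a smaller share of messenger RNA in the total RNA are both open and were not tested.

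Of 54 groups of values checked for a sample far from the others, 8 had one, where chance gives about 1 in 20 for independent groups. These groups are not independent. They mix scan days, and the identifiers were chosen from these same arrays. Heart maintenance replicate 7, the only array of scan day 3, stood apart in spike-in signal (12.67). It also did so in the percent of probes well above background (42.3) and in Contig532 (-3.94). Red muscle full-ration replicate 3, the only one of its group on scan day 5, stood apart in spike-in signal (13.31). It also did so in cDN04P0004I22.F.ab1 (1.97) and in cDN03P0005F15.F.ab1 (0.61). Spike-in signal followed scan day. White muscle maintenance replicate 8 stood apart in CUST_7161_PI419285597 (-0.40) and cDN09P0001L11.F.ab1 (-0.35).

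Responses to ration differed between tissues by an interaction test in 1110 probes for heart and white muscle, 614 for heart and red muscle and 1241 for red and white muscle. Among printed identifiers, Contig1322 differed by 3.72 between heart and white muscle and 3.31 between heart and red muscle. CUST_7161_PI419285597 differed by 3.74 between heart and white muscle and 3.51 between red and white muscle, and cDN09P0001L11.F.ab1 by 3.80 and 3.31. Between red and white muscle cDN04P0004I22.F.ab1 differed by 5.73, cDN03P0005F15.F.ab1 by 4.42, cDN11P0005D24.F.ab1 by -3.35 and cDN11P0006J21.F.ab1 by -3.43. Between heart and red muscle cDN11P0005D24.F.ab1 differed by 4.28 and cDN11P0006J21.F.ab1 by 3.72. The falls in white or red muscle could hardly be measured in the other tissues: at full ration CUST_7161_PI419285597 was well above background on 2 of 7 hearts and 4 of 8 red muscles, cDN09P0001L11.F.ab1 on 1 and 3, cDN11P0005D24.F.ab1 on 0 of 7 hearts and 0 of 5 white muscles, and cDN11P0006J21.F.ab1 on 1 and 2. So their differences do not show an unequal response. Within scan days, with 1 full-ration red muscle array, cDN04P0004I22.F.ab1 and cDN03P0005F15.F.ab1 turned to -1.19 and -0.99. There the differences of Contig1322 were 3.27 and 4.71, those of cDN11P0005D24.F.ab1 3.87 (heart and red muscle) and -3.32 (red and white muscle), and those of cDN11P0006J21.F.ab1 2.67 and -4.09; none of these passed in this smaller fit, with SE between 0.95 and 1.22, against 0.68 to 0.87 over all arrays. With slide as a block none of the 12 passed.

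The spike-in control spots, which enter no comparison of expression, stood above the negative controls by 11.11 on the log2 scale on scan day 5 and by 3.83 on scan day 2.

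Other splits of the same arrays, up to 100 per comparison with the real one, showed how often an arbitrary split called as many probes. For the ration counts only the real split (1 of 100) reached 5286 in heart, 2693 in white muscle and 4999 in red muscle. The other splits called 2437, 1444 and 33 at most. A split of white muscle by scan day was not among them. It set the 6 arrays of day 5 against the 4 of other days, with the rations balanced on both sides, and called 2173 probes. For the differences of response 1 of 100 splits reached 1110 (highest other 42) and 1 reached 614 (highest other 3), while 2 of 100 reached 1241, since another split called 1740. These splits did not keep the numbered pairs of red and white muscle. For the tissues only the real splits (1 of 100) reached 14860, 11370 and 12926, against 11799, 4878 and 9113; of the 32 splits that part all 5 numbered pairs of red and white muscle, 1 reached 12926, the real one (highest other 8040). For all 9 counts the share of splits with as many calls was under 0.05, which says nothing about scan day or slide. Arrays that share a scan day, slide or number may not be exchangeable, so this share is not an exact chance level. For the tissues the outcome was nearly fixed in advance, since every other split mixes tissues. Splits with many calls point to structure among the arrays.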

How the results depend on the processing

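The alternatives on scan day, a random slide block, the spike-in, single-array scan days and fewer arrays were chosen after seeing the data. Counts were 5286, 2693 and 4999 for ration in heart, white and red muscle, 1110, 614 and 1241 for differences of response (heart-white, heart-red, red-white), and 14860, 11370 and 12926 for the same pairs of tissues. Counts not given for an alternative stayed within 1.5 times, and where no value below bears on it the cause was not tested. The authors' values gave 5288, 2690 and 4992 for ration. Gene set tests were not run. Signal over background limited the dim probes.

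After normexp background correction the counts were 1320 in heart and 179 in white muscle, 20, 32 and 44 for the differences of response, and 7549 for heart-red tissues. The spread of 3 arrays, heart full-ration replicate 2, white muscle maintenance replicate 5 and red muscle full-ration replicate 1, was larger after normexp, and that of 31 was smaller. Normexp without these 3 gave 9937, 462 and 12601 for ration, and 1719 for heart-white and 7276 for red-white responses. Of the 9937 and 12601, 3740 and 3513 were calls of the reported fit in the same direction. So the heart and white muscle counts after normexp rose without these arrays, white muscle to fewer than reported; they were left out together, so no value shows which of them moved a count. Leaving them out on the reported scale gave 565 for heart-white and 359 for heart-red responses.

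Without a filter 8666 probes were called in heart, 9114 in red muscle and 407 for heart-red responses. With only probes above background on every array, fewer were tested, and the counts were 2825 in heart, 2136 in red muscle, 337 and 453 for heart-red and red-white responses, and 6192, 4956 and 5780 for tissues. With only the groups compared in the fit, white muscle gave 908, heart-white responses 697 and red-white responses 755. A plain equal-variance test per probe gave 8263, 4500 and 8316 at an unadjusted p under 0.05, and 696 in white muscle after adjustment. Array weights gave 7744 in red muscle and 1784, 2309 and 2335 for responses.

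With slide as a fixed block the counts were 213, 897 and 11 for ration, 30, 11 and 6 for responses and 7085, 1791 and 7967 for tissues. As a random block slide gave 2370 in red muscle and 429, 168 and 260 for responses. With scan day as a block the counts were 145 in red muscle, 410 and 85 for heart-white and red-white responses, and 5151 and 8567 for heart-red and red-white tissues. Within scan day, with fewer arrays, ration gave 3365, 424 and 12, and scaled to the spike-in 11997, 328 and 13, of which 0.43% were higher in heart. Differences of response within scan day were 580, 60 and 36. Without scan days 3 and 4 heart gave 3247, and heart-white and heart-red responses 647 and 398.

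Among 12 ration changes, 12 differences of response and 6 tissue differences of identifiers, the direction turned for 2 identifiers chosen in red muscle. Clone cDN04P0004I22.F.ab1 went to -0.35 with slide and -0.56 with scan day as a block, to -0.72 within scan day and to -1.13 there scaled to the spike-in. Clone cDN03P0005F15.F.ab1 went to -0.55 within scan day and to -0.97 there scaled to the spike-in. Between red and white muscle the difference of cDN04P0004I22.F.ab1 went to -0.59 with slide and -1.08 with scan day as a block and to -1.19 within scan day, and that of cDN03P0005F15.F.ab1 to -1.10 with slide as a block and -0.99 within scan day. Other alternatives ended a call without turning it 29 times for ration and 50 times for differences of response. When 1 array was left out no ration or tissue call of an identifier was lost, while 4 differences of response lost theirs: Contig1322 between heart and red muscle (3.14 without heart maintenance replicate 7, 3.105 without red muscle maintenance replicate 1), cDN11P0006J21.F.ab1 between heart and red muscle (3.25 without heart maintenance replicate 7), cDN09P0001L11.F.ab1 between red and white muscle (3.03 and 2.96 without white muscle maintenance and full-ration replicates 7) and cDN04P0004I22.F.ab1 between red and white muscle (4.84, 5.297 and 4.78 without white muscle maintenance replicate 7, full-ration replicate 7 and maintenance replicate 8).

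Leaving out each array gave 3188 to 5565 in heart, lowest without maintenance replicate 7, and 660 to 1235 for heart-white responses, with 660 and 669 without heart maintenance replicates 6 and 7. Heart-red responses gave 352 to 1000, and moved over 1.5 times without heart maintenance replicate 6 (371) or 7 (352), heart full-ration replicate 1 (391), red muscle maintenance replicate 1 (360), 3 (376) or 6 (368), or red muscle full-ration replicate 3 (1000). Red-white responses gave 697 to 1979, with 697 without white muscle maintenance replicate 7, 800 without red muscle maintenance replicate 3 and 1979 without red muscle full-ration replicate 3.

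The replicate numbers were taken to pair red with white muscle at full ration, where the replicate block gave 12838. In the other groups the check on correlations was not met, which leaves pairing open. Between heart and red muscle at full ration, replicates 1 and 4 gave -0.02 and -0.04 with their own number. Crosswise, heart 1 with red muscle 4 gave 0.37, and heart 4 with red muscle 1 gave 0.44. The reason was not tested. Deviations of same-numbered arrays of the rations of a tissue correlated from -0.20 to 0.21 (12 pairs), and those of tissues of a ration from -0.04 to 0.43 (24 pairs, 17 over 0.1); 20 of 30 arrays correlated best with their own number in another tissue, a hint from the data and not the design. With the number as a replicate block the ration counts were 23, 278 and 625, and with ration and number as a replicate block heart-red and red-white responses were 199 and 551. As a random block ration and number gave 1705 and 1101 for heart-white and heart-red responses.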

Other observations

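Probes typical of one tissue were followed in another tissue's response to ration, using sets taken from arrays outside that response; these set tests were chosen after seeing the data. In red muscle, of 2484 probes at least 4-fold higher in white muscle than in heart at full ration, 831 were higher and 118 lower at maintenance and 1535 did not pass. Their median log2 change was 0.45, against -0.01 for other probes (camera, adjusted p = 1.16e-09 with a preset correlation, adjusted p = 0.126 with an estimated correlation). Within scan day 5 the median was 0.15, against -0.03 (camera, adjusted p = 0.754 with an estimated correlation), so the shift did not pass there. In heart, of 1218 probes higher in white than in red muscle, 162 were higher and 67 lower at maintenance and 989 did not pass, with a median of 0.50 against -0.03 (adjusted p = 0.000333 preset, adjusted p = 0.642 with an estimated correlation). Among the 330 of these that were well above background on every array the median was 0.00080. The other 4 sets did not pass with either correlation.

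The responses of heart and white muscle to ration share a direction, and a hypothesis is a common response to ration. Heart within scan day 1 and white muscle within scan day 5, which share no array, slide or day, correlated across probes at r = 0.35. Among probes well above background on every array r was 0.44, so probes at the signal floor were not needed for the correlation. This filter cannot exclude other effects of lower signal of the maintenance arrays in both tissues. Of the probes called within both scan days 125 had the same direction, against 32.4 for independent lists, and 5 the opposite one. Arrays of both tissues may come from the same fish, as they share replicate numbers. From arrays with no number in common within a ration r was 0.0954 (-0.06 to 0.22 without 1 array), and 35 of 350 choices of as many arrays gave a value as low (median 0.25). Within scan days, with 1 maintenance heart, r was 0.169, the lowest of 63 such choices (median 0.29); this value and both sets of choices were added after 0.0954 was seen. A common response to ration and the same fish in both tissues are each consistent with part of these values and stay open, and an effect of processing shared by maintenance samples before hybridisation was not tested.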
